A study of Gallus gallus with 5 samples.

How the data were processed

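RNA-seq measured the polyadenylated RNA of the chicken (Gallus gallus) blastoderm, the disc of embryonic cells on the yolk of a laid egg. Per the labels, 3 libraries came from blastoderms stored for 7 days at 4, 16 or 24 °C, 1 from blastoderms incubated for 4 h at 37 °C and 1 from unstored blastoderms. The labels' protocols describe isolation of total RNA with an RNeasy kit, poly(A) selection, TruSeq libraries and paired reads from an Illumina HiSeq. How many blastoderms entered a library is not given in the sources used here. Each condition had 1 library, so the data hold no replicates. No p-value, standard deviation between replicates or standard error is given for any comparison, and each difference lies between libraries and has no replicate check.

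The authors deposited FPKM values, fragments scaled by transcript length and by the number of mapped fragments, for each RefSeq transcript accession, per the file headers. TopHat2 2.0.8, Cufflinks 2.0.2 and the build galGal4 are named in the submitters' processing notes, which give no role for each. The annotation release and any scaling between libraries are not given in the sources used here. The values carry 2 decimals, and FPKM summed to between 333528 and 389061 per library over 32188 rows. FPKM depend on transcript length, and Cufflinks divides reads between isoforms by a model, so low values are not whole multiples of a read. The depth behind a value is therefore unknown, and no interval or detection limit was computed. An exact 0 can be a failed estimate, so a gene at 0 is described only as listed at 0, and no fold is given for it.

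The rows carry accessions without gene names. Names were taken from a RefSeq table of the assembly GRCg7b, a different build from the authors' one, by matching accessions without their version. No coordinates of that table were used. Of the 32188 rows, 12609 (39.2%) received a symbol, 5414 of 5787 curated (NM) and 7195 of 26401 predicted (XM) accessions, and only 636 matched with the same version. Rows with a symbol held between 70.4% and 72.0% of the FPKM of a library. FPKM of rows with the same symbol were summed, which gave 10102 genes, 8510 of them with 1 row. A gene's value leaves out any isoform whose accession was not matched, so a shift between isoforms can appear as a change of the gene. Copies of multigene families share reads, and their values, such as those of histone genes, are uncertain.

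Genes entered with FPKM of at least 1 in 1 or more of the 5 libraries, which kept 7733. Differences are on the log2(FPKM + 1) scale, which understates the change of low genes. A gene was counted as at least 2-fold higher or lower when this difference reached 1, with FPKM above 0 in both libraries. Genes listed at 0 were counted apart. Values were compared as deposited. The median of all genes then differed from 0 by more than 0.1 in 4 of 10 pairs of libraries, by 0.12 for incubated against unstored, 0.10 for 4 °C against unstored, -0.15 for 16 °C against 4 °C and -0.15 for 16 °C against incubated.

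Before the data were examined, 31 gene lists were fixed, with the comparisons, the size rule and the alternatives. For each list, the median log2 ratio was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A median outside the central 95% of these was called apart from matched lists, which takes the shift of all genes into account. This describes these libraries and does not test the conditions. About 5% of lists of randomly drawn genes, or 1.5 of 30 per comparison, lie outside by chance. Members of a fixed list can vary together, so more of the 30 measured lists could lie outside without an effect of the condition. Lists share some members, and 21 members were matched through an older symbol. Mitochondrially encoded genes had no measured member and were not analysed here.

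The genes named in the text follow a rule fixed at the same time. They have a symbol that is not a placeholder, FPKM above 0 in the libraries compared and at least 5 in 1 of them, and the largest differences. The rule took the 12 highest and 12 lowest for incubated against unstored, and the same for the smallest change over the 3 stored libraries against unstored. It took 4 and 4 for each storage temperature against unstored, for 16 °C against 4 °C and for 24 °C against 16 °C. It took 10 and 10 for 24 °C against 4 °C, and 8 and 8 each for storage against incubation and against both other libraries. Members of the fixed lists were named as examples, and the 3 highest genes listed at 0 in the other library could be named without a fold. Not every gene that the rule took is named in the text.

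The alternatives were a pseudocount of 0.1 or 5, no filter, a mean FPKM of at least 5, median-ratio size factors, FPKM rescaled to 1000000 per library, the highest row per gene in place of the sum, and leaving out each stored library where all 3 were required. Rescaling to 1000000 raised every value, as FPKM summed to at most 389061 per library, while the pseudocount stayed at 1. Low genes therefore weighed more under that setting, apart from any change of scale between libraries. Counts over all transcript accessions and over genes with 1 matched accession were added after seeing the data. Comparisons that share the unstored library were set beside 100 simulations of unchanged libraries, with noise from the closest pair of libraries, 4 °C and unstored.

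The size rule was tested on simulated libraries for 24 °C against unstored with 7733 genes, of which 200 were changed. At a true 4-fold change 99.5% of changed genes were recovered, at 8-fold 100% and at 2-fold, which lies on the threshold, 42.5%. The changed genes were drawn only among genes with a mean FPKM of about 5 or more. Recovery was therefore not measured for genes of low FPKM, whose change is understated on the scale used. The shares given cannot be carried over to such genes. Between 3 and 14 of 7533 unchanged genes passed. The simulated noise came from the closest pair, 4 °C and unstored, in which 56 genes passed. The noise of the other pairs is unknown, so these numbers give no rate of false calls for them. In the same simulation 5 of 200 random lists lay outside the central 95% of matched lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.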

Results

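The series profiled messenger RNA of the chicken blastoderm after storage and after incubation. Its title names late apoptosis and arrest of the cell cycle at G2/M during dormancy, the pause in development that a laid egg enters when it is kept cool. The 5 libraries came from unstored blastoderms, from blastoderms incubated for 4 h at 37 °C, and from blastoderms stored for 7 days at 4, 16 or 24 °C, with 1 library each. The number of genes with FPKM of at least 1 was 6928 in the unstored library, 7220 in the incubated library, and 7069, 7057 and 7134 in the libraries stored at 4, 16 and 24 °C. The 10 highest rows held between 4.69% and 6.07% of the FPKM of a library.

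The library stored at 4 °C was the closest to the unstored library, and the libraries stored at 16 and 24 °C resembled each other. The log2 ratio of 4 °C to unstored had a standard deviation of 0.27 over 7697 genes, against 0.47 for 24 °C to 16 °C, 0.61 for incubated to unstored, 0.72 for 16 °C to unstored and 0.78 for 24 °C to unstored. At least 2-fold differences from unstored were seen in 56 genes at 4 °C, 848 in the incubated library, 1261 at 16 °C and 1447 at 24 °C. The closest pair has the smallest spread of all pairs and itself joins different conditions. Its spread holds technical and biological parts together and does not give the noise of the other pairs.

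**Figure D1:**
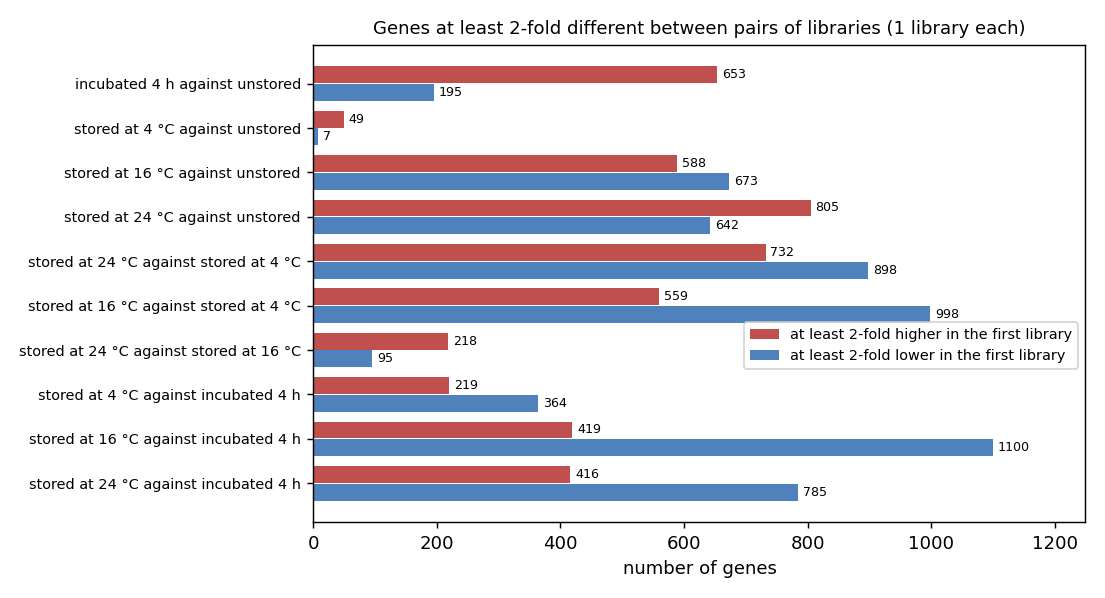
Number of genes (x axis) at least 2-fold higher (red) or lower (blue) in the first library of each pair (y axis), on the log2(FPKM + 1) scale with 1 library per condition. The pair of 4 °C and unstored has the fewest genes, 49 higher and 7 lower, and 16 °C against incubated has the most lower genes, 1100.

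Incubation for 4 h at 37 °C was compared with the unstored state to describe the blastoderm as it resumes development. Genes of the early endoderm and of the primitive streak, through which cells move inward to form the germ layers, were higher after incubation. HNF4A, a transcription factor of endoderm and liver, had the largest difference, from FPKM 0.83 to 26.3 (log2 ratio 3.90). CER1, a secreted antagonist of Nodal made by the hypoblast, went from 0.24 to 8.18 (2.89). Of 17 measured genes of hypoblast and endoderm, 7 were at least 2-fold higher and 1 was lower. They included APOA1 (2.22), an apolipoprotein, and the transcription factors FOXA2 (1.39) and SOX17 (1.34), and the lower gene was OTX2 (-1.38). Of 33 genes of streak, mesoderm and axis signalling, 11 were higher and 1 was lower, with TBXT (brachyury, 2.05) and SNAI1 (1.91) among the higher. The medians of these lists were 0.81 and 0.66, both above the central 95% of matched lists. With only genes of 1 matched accession the hypoblast median was 0.58 and lay within it.

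Other genes among the highest after incubation were SLC1A3 (3.36), a glutamate transporter, ITGAV (2.89), an integrin subunit, TNPO1 (2.85), a nuclear import receptor, ADAM19 (2.77), a metalloprotease, BPIFCB (2.71), SMARCA2 (2.69), a chromatin remodelling ATPase, ST3GAL1 (2.56), a sialyltransferase, CD40 (2.52), PITX3 (2.51) and CNTN2 (2.49). The lowest was TSC22D1, with FPKM 61.6 in the unstored and 7.5 in the incubated library (-2.88). TACR1, the receptor of substance P (-2.41), the transcription factors SOX14 (-2.18) and FOXB1 (-1.75), the cofactor VGLL2 (-1.87) and the actin-capping protein TMOD1 (-1.84) followed. FAM46B (-2.17), ILDR2 (-1.88), KCNK5 (-1.80), NRF1 (-1.76) and PTGER3 (-1.73) were also among the 12 lowest.

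Genes that initiate apoptosis were higher in the incubated library as a group, with a median of 0.54 over 22 genes, above matched lists. CASP2 (1.46) and BMF (1.10) were at least 2-fold higher and none was lower. The unfolded protein response and integrated stress response had a median of 0.37 and autophagy and lysosome genes a median of 0.48, both above matched lists. Within the latter, CTSV, a lysosomal protease, reached 1.04. Of 28 heat shock and chaperone genes, 3 were higher and none lower, among them SERPINH1 (2.01), the collagen chaperone, and DNAJA1 (1.58), yet the list median of -0.05 lay within matched lists while its mean was 0.15. RBM3, a cold-inducible RNA-binding protein, had FPKM 299 in the unstored and 101 in the incubated library (-1.56). The G2/M list had a median of -0.28, below matched lists, with CCNB1 (-1.08) and CKS1B (-1.28) lower and ANLN (1.28) higher. With only genes of 1 matched accession it was -0.25 and lay within them. Histone genes (-0.77), the oocyte list (-0.47 over 5 genes) and the muscle and neural list (-0.33 over 9 genes) also lay below. The histone transcripts had FPKM mostly under 10, partly lack poly(A) tails, and lay within matched lists at a mean FPKM of at least 5.

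In all, 653 genes were at least 2-fold higher and 195 lower after incubation among 7700 compared. With median-ratio size factors these counts were 496 and 286, which moves the share of higher genes from 77.0% to 63.4%.

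Storage at 4 °C for 7 days was compared with the unstored state as the coldest of the storage conditions. Few genes differed, and those that did were mostly higher and included genes of the hypoblast and of the streak. Of 7697 genes, 49 were at least 2-fold higher and 7 lower. HNF4A went from FPKM 0.83 to 5.69 (1.87). SOX17 (1.29), FOXA2 (1.21), APOA1 (1.09), HHEX (1.05) and CER1 (1.01) were also higher, 7 of the 17 hypoblast genes in all, and so were 5 of the 33 streak and axis genes, among them EOMES (1.06) and GSC (1.04). The medians of these lists, 0.81 and 0.40, lay above matched lists, whose central 95% reached from -0.03 to 0.26 for the hypoblast list. AMER1 (2.70), a regulator of Wnt signalling, BPIFCB (1.74) and LGMN (1.56), a lysosomal protease, had the other largest values. ILDR2 (-1.42), PCF11 (-1.20), SUSD6 (-0.96) and the clock gene PER2 (-0.93) had the lowest.

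At 4 °C the chaperone list (0.18), the G2/M list (0.14), the autophagy and lysosome list (0.22), the list of extra-embryonic ectoderm and epithelial barrier (0.22) and the histone list (0.24) also lay above matched lists, though no more than 1 gene of any of them was at least 2-fold different. With only genes of 1 matched accession the medians of the G2/M (0.14), epithelial (0.21) and histone (0.24) lists were about as large but lay within matched lists, and the histone list also under most other settings. The ribosomal protein list lay below, at -0.02, where the median of all genes was 0.10. With median-ratio size factors 31 genes were higher and 13 lower, so that the share of higher genes went from 87.5% to 70.5%.

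Storage at 16 and 24 °C was compared with the unstored state to describe dormancy at warmer temperatures. In both libraries the lists of G1/S and DNA replication and of heat shock proteins and cytosolic chaperones lay below matched lists, and the list of autophagy and lysosome genes lay above. Of 39 genes of G1/S and DNA replication, 9 were at least 2-fold lower at 16 °C and 12 at 24 °C, and none was higher. RRM2, a subunit of ribonucleotide reductase, had FPKM 279 in the unstored library, 48.3 at 16 °C (-2.50) and 60.3 at 24 °C (-2.19). Cyclins CCNE1 (-1.78 and -2.19) and CCNE2 (-1.55 and -2.16), the replication licensing inhibitor GMNN (-1.66 and -1.75) and the helicase subunit MCM3 (-1.60 and -1.50) were also lower at both temperatures. The list medians of -0.73 and -0.71 lay below all of the matched lists at 16 °C and at 24 °C.

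Of the 28 heat shock and chaperone genes, 11 were at least 2-fold lower and 2 higher at 16 °C, and 12 were lower and none higher at 24 °C, with medians of -0.65 and -0.87, below matched lists. HSPH1, a co-chaperone of HSP70, was among the genes with the largest differences in the data, with FPKM 113 in the unstored library, 14.4 at 16 °C (-2.89) and 11.5 at 24 °C (-3.19). The abundant HSP90AA1 went from 2980 to 639 (-2.22) and 985 (-1.60), HSPA8 from 2455 to 949 (-1.37) and 1085 (-1.18), and the mitochondrial chaperonin HSPD1 from 545 to 173 (-1.65) and 187 (-1.54). HSPB9 differed between the temperatures, with FPKM 201 in the unstored library, 687 at 16 °C (1.77) and 64.7 at 24 °C (-1.62).

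Autophagy and lysosome genes lay above matched lists, with medians of 0.28 at 16 °C and 0.71 at 24 °C, and 8 and 9 of 33 at least 2-fold higher. The autophagy receptor SQSTM1 went from FPKM 35.6 to 143 at 16 °C (1.98) and 193 at 24 °C (2.41), the lysosomal membrane protein LAMP1 from 122 to 354 (1.52) and 416 (1.76), and ATG9A reached 1.58 and 1.94. Without a filter on low values the median at 16 °C was 0.16 and lay within matched lists. The proteasome list was above matched lists at both temperatures (0.14 and 0.11) with no gene at least 2-fold higher and 2 lower, and ribosomal protein genes were above at 24 °C (0.22). Histone genes lay below (-0.69 and -0.84), but within matched lists at a mean FPKM of at least 5.

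The list of 26 pluripotency and epiblast genes lay within matched lists at 16 °C (-0.27) and 24 °C (-0.30), with 8 and 6 genes at least 2-fold lower and 2 higher at each temperature. NANOG had FPKM 526 in the unstored library, 225 at 16 °C (-1.22) and 223 at 24 °C (-1.23). SOX3 (-1.88 and -1.39), LIN28A (-2.0 and -1.46) and the DNA methyltransferase DNMT3B (-1.23 and -1.98) were among the other lower genes.

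Immediate early genes, which respond within minutes to growth factors or stress, were higher in the library stored at 16 °C. Of 24 measured, 11 were at least 2-fold higher and 2 lower, and the median of 0.69 lay above matched lists. JUN went from FPKM 52.7 to 549 (3.36) with 64.2 at 24 °C, the phosphatase DUSP8 from 10.6 to 102 (3.15), the matricellular gene CCN2 from 13.3 to 113 (3.0) and DUSP1 from 18.5 to 97.1 (2.34). MYC (-1.36) and DUSP4 (-1.23) were the lower genes. Some chaperones of the endoplasmic reticulum were higher at 16 °C too, HSPA5 (BiP) from 187 to 1334 (2.83) and HSP90B1 from 159 to 420 (1.39), as was the stress kinase EIF2AK3 (2.01). The unfolded protein response list as a whole had a median of 0.07 there, within matched lists, with 4 genes higher and 1 lower. At a mean FPKM of at least 5 it was 0.25 and lay above them. The highest genes at 16 °C by rank were TNPO1 (3.44), JUN, DUSP8 and the metalloprotease MMP9 (3.02). The lowest were RABGGTB (-4.43), a subunit of the enzyme that prenylates Rab proteins, SOX14 (-3.24), GRK6 (-2.91) and HSPH1. Genes of the antioxidant response had a median of -0.43, below matched lists.

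At 24 °C the hypoblast and endoderm list had a median of 0.90, above matched lists, with 8 genes higher and 2 lower. APOA1 went from FPKM 21.4 to 198 (3.16) and CER1 reached 1.79, while GATA5 was -1.19. Without a filter on low values this median was 0.25 and lay within matched lists. TBXT had FPKM 4.97 in the unstored library and 27.5 at 24 °C (2.26), and the streak list of 33 genes had a median of 0.29, within matched lists. The highest genes at 24 °C were FBLN1 (3.21), an extracellular matrix protein, APOA1, STX7 (3.11), a syntaxin of late endosomes, and TNPO1 (3.02). The lowest were PRDX3 (-4.12), a mitochondrial peroxidase, HSPH1, APOO (-3.03), a protein of the mitochondrial inner membrane, and TACR1 (-3.00). The apoptosis initiation list (0.57) and the unfolded protein response list (0.22) lay above matched lists. Without the filter on low values the latter was 0.21 and lay within. Of the lists of other sources, the egg white list of 5 genes lay above matched lists at 24 °C (1.78), led by TF (2.52), a transferrin, AVD (1.81), avidin, and SPP1 (1.78), at FPKM of 14.6, 11.6 and 5.99. The muscle and neural list lay below (-0.66).

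At 16 °C 588 genes were at least 2-fold higher and 673 lower among 7689, and at 24 °C 805 were higher and 642 lower among 7690. With FPKM rescaled to 1000000 per library the share of higher genes went from 46.6% to 60.5% at 16 °C and from 55.6% to 67.0% at 24 °C. This setting also gives low genes more weight, so these shifts are not due to scaling between libraries alone. For 24 °C against 16 °C, with nearly equal FPKM sums, it moved the counts from 218 and 95 to 388 and 168. With median-ratio size factors 718 genes were higher and 751 lower at 24 °C, a share of 48.9%, so the balance of higher and lower genes there depends on the scaling.

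The lists closest to the title of the series were examined at all 3 storage temperatures. Of 40 genes of G2/M progression and mitosis, none was at least 2-fold different at 4 °C, 2 were lower at 16 °C and 6 at 24 °C, and none was higher. CCNB1, the mitotic cyclin, had FPKM 359 in the unstored library, 429 at 4 °C, 184 at 16 °C (-0.96) and 154 at 24 °C (-1.22). CKS1B (-1.75 and -1.81) and PTTG2 (-1.23 and -1.22) were lower at 16 and 24 °C, and AURKB (-1.20), BIRC5 (-1.13) and SMC2 (-1.02) at 24 °C. CDK1 was -0.53 at 16 °C and -0.86 at 24 °C, PLK1 -0.08 and -0.35, and CENPE 0.88 and 0.88. The list medians of -0.11 at 16 °C and -0.33 at 24 °C lay within matched lists.

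Genes of late apoptosis, its execution and DNA fragmentation, had medians of 0.08 at 4 °C, -0.10 at 16 °C and -0.19 at 24 °C, all within matched lists. The list mixes genes that carry out apoptosis with genes of proteins that caspases cut, so its median joins genes of different roles. Transcript levels also do not count dying cells, so the late apoptosis of the title was neither shown nor excluded. Of 24 genes none was at least 2-fold different at 4 °C, 1 was higher and 3 lower at 16 °C, and 4 were higher and 2 lower at 24 °C. CASP6 was -0.28, 0.70 and 0.68 at 4, 16 and 24 °C. The lamin genes LMNB1 (-1.88 and -1.91) and LMNB2 (-1.17 and -1.59), whose proteins caspases cut, were lower at 16 and 24 °C, and HMGB1 (-1.02) at 16 °C. The nuclease subunit DFFB (1.19), gelsolin (GSN, 1.09) and the calpains CAPN1 (1.73) and CAPN2 (2.05) were higher at 24 °C. The list of 22 initiation genes had medians of 0.10 at 4 °C and 0.11 at 16 °C, within matched lists, and 0.57 at 24 °C, above them. Its median was also above them in the incubated library (0.54), and at 24 °C against incubated it was -0.13, within matched lists. Of its members, CYCS, cytochrome c, went from FPKM 442 to 149 (-1.56) and 138 (-1.67) and BAK1 was higher (1.28 and 1.43) at 16 and 24 °C. BMF was -1.17 at 16 °C and 0.72 at 24 °C. The anti-apoptotic list lay within matched lists at 4 °C (0.01), 16 °C (0.17) and 24 °C (-0.04), with 1 gene higher and 1 lower at 16 °C, and 1 higher and 2 lower at 24 °C. The higher gene was BCL2 (1.57 and 1.95), and BIRC5 was among the lower genes at 24 °C (-1.13).

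**Figure D2:**
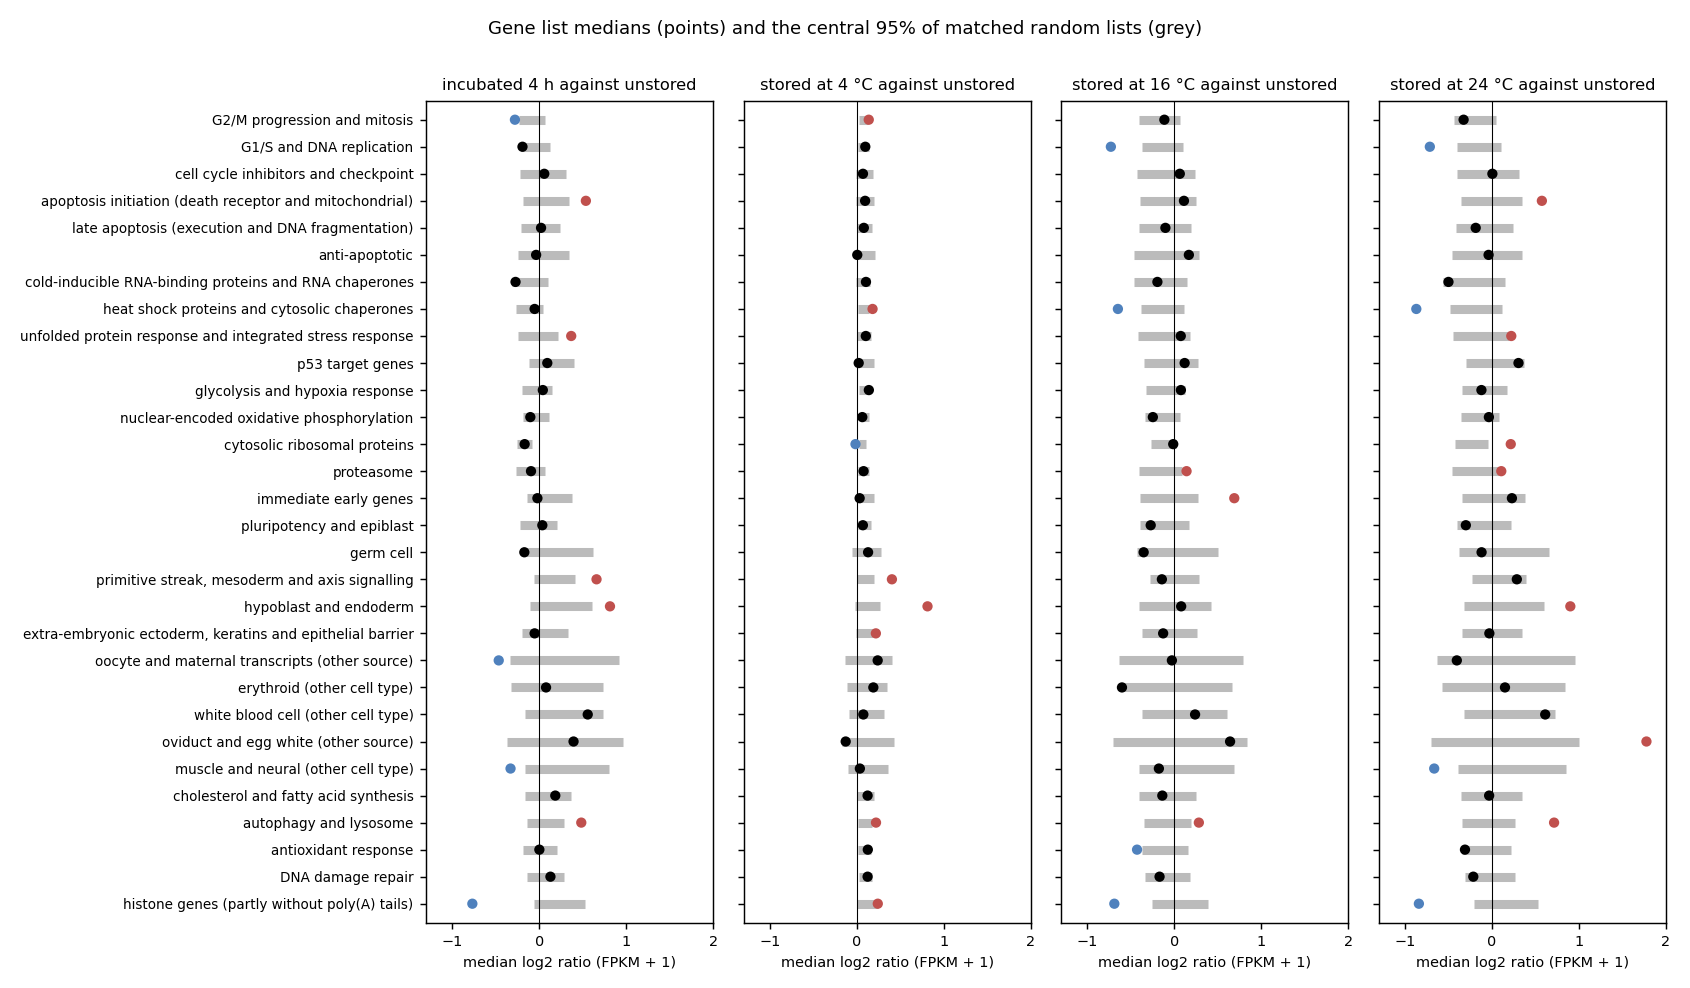
Median log2 ratio of each gene list (points, x axis) against unstored for incubation and for storage at 4, 16 and 24 °C, with the central 95% of 10000 matched random lists in grey and medians above it in red or below it in blue. The G1/S and chaperone medians lie far below the grey range at 16 °C (-0.73 and -0.65) and 24 °C (-0.71 and -0.87), and the immediate early median above it at 16 °C only (0.69) among these 4 panels.

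The remaining lists lay within matched lists in all 4 comparisons with unstored. Those were the lists of cell cycle inhibitors (0.06 in the incubated library, 0.07 at 4 °C, 0.06 at 16 °C and 0.01 at 24 °C), cold-inducible RNA-binding proteins (-0.27, 0.11, -0.19 and -0.50), p53 targets (0.09, 0.02, 0.12 and 0.31) and glycolysis and hypoxia (0.04, 0.14, 0.08 and -0.12). The same held for oxidative phosphorylation (-0.10, 0.06, -0.25 and -0.03), germ cells (-0.17, 0.13, -0.35 and -0.12), cholesterol and fatty acid synthesis (0.18, 0.12, -0.14 and -0.03), DNA repair (0.13, 0.12, -0.17 and -0.21), erythroid cells (0.08, 0.19, -0.60 and 0.15) and white blood cells (0.56, 0.08, 0.24 and 0.61). The glycolysis median at 16 °C was above 0 while its mean was -0.13. The p53 target median at 24 °C lay above matched lists under 4 other settings, for example 0.53 with FPKM rescaled to 1000000 per library. Of 30 lists, 9 lay apart in the incubated library, 8 at 4 °C, 7 at 16 °C and 11 at 24 °C. Lists of randomly drawn genes would give 1.5, but members of a fixed list can vary together, so the excess does not measure an effect of the conditions.

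The 3 stored libraries had few differences from unstored in common. At least 2-fold higher values in each of them were found for 10 of 7666 genes, and lower values for 0. Leaving out the library at 4 °C gave 378 and 381, so that library decided these counts. By the smallest change over the 3 libraries the highest genes were TNPO1 (1.89), BPIFCB (1.32), HID1 (1.27), ANXA8L1 (1.24), STRA6 (1.22), a retinol transporter, PITX3 (1.14), APOA1 (1.09), VDAC1 (1.04), the mitochondrial anion channel, LIMS2 (1.0), CRHR1 (0.98), ITGAV (0.91) and UPK3BL (0.84). Of these 12, all were also higher in the incubated library than in the unstored one. They were chosen as higher than that same unstored library, which favours genes with a low value in it. Their values after incubation are therefore no separate evidence of a change common to storage and incubation. The lowest were CCDC85C (-0.60), HIST1H46L6 (-0.56), ILDR2 (-0.53), the chemokine CXCL12 (-0.51), FAM171B (-0.50), GAR1 (-0.47), PLPP3 (-0.47), RSPRY1 (-0.45), NNT (-0.44), CCDC88B (-0.43), ATP5F1AW (-0.43) and PCDH1 (-0.43).

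Against the incubated library, 18 genes were at least 2-fold higher and 100 lower in each of the 3 stored libraries, among 7670. MERTK, a receptor for apoptotic cells (1.56), DUSP1 (1.40), TM7SF3 (1.22), the cholesterol transporter ABCA1 (1.22), BORCS6 (1.13), SH2B3 (1.08), HTT (1.07) and FZD6 (1.07) had the highest smallest change. MERTK had FPKM 9.37 after incubation, between 29.7 and 35.0 in the stored libraries and 31.8 in the unstored library. NNT (-2.08), HNF4A (-2.03), the calcium channel TRPV6 (-2.0), SLC1A3 (-1.93), PDE4DIP (-1.74), MOGAT2 (-1.65), CALD1 (-1.62) and CPLX1 (-1.60) had the lowest. Each gene named here on either side differed from the incubated library in the same direction in the unstored library. These differences therefore do not set the stored libraries apart from the unstored one. Leaving out the library at 4 °C gave 211 and 592 genes, and leaving out the one at 24 °C gave 41 and 176.

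No gene was at least 2-fold higher or lower in each stored library than in both the unstored and the incubated one. Among the widest gaps were 0.61 for SH2B3, an adaptor protein, 0.55 for TTC7B, 0.53 for HHEX, 0.50 for AIM1, 0.49 for YPEL5, 0.44 for SNX10 and 0.44 for RDH5. On the lower side they were -0.68 for PDE4DIP, -0.45 for RSPRY1, -0.44 for NNT, -0.39 for HMGA2, -0.37 for LRRN4, -0.29 for LYPLAL1, -0.29 for LRRN1 and -0.28 for CEP76. Without the library at 4 °C 91 genes were higher and 181 lower than in both.

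Storage temperatures were compared with each other, which leaves out the shared unstored library. At 24 °C against 4 °C 732 genes were at least 2-fold higher and 898 lower, a share of higher genes of 44.9% that went to 63.0% with FPKM rescaled to 1000000 per library. The highest were LCP1 (3.30), an actin-bundling protein of white blood cells, SYNM (2.88), STX7 (2.85), TAPBP (2.77), FBLN1 (2.76), the coagulation factor F10 (2.76), PDE8B (2.75), FAM219A (2.71), ERAP1 (2.69) and TF (2.65). TAPBP and ERAP1 both act in antigen presentation. The lowest were PRDX3 (-4.54), HSPH1 (-3.49), CCNA1 (-3.32), APOO (-3.21), EOMES (-3.19), TMOD1 (-3.09), TACR1 (-3.06), PPAT (-3.02), PUS3 (-2.93) and NEFM (-2.89). At 16 °C against 4 °C 559 genes were higher, led by DUSP8 (3.68), AADACL3C (3.37), CCN2 (3.35) and JUN (3.28), and 998 were lower, led by RABGGTB (-4.43), HSPH1 (-3.18), SOX14 (-2.92) and the riboflavin transporter SLC52A3 (-2.89). With median-ratio size factors these counts were 714 and 771, a share of higher genes of 48.1% in place of 35.9%, and with FPKM rescaled to 1000000 per library they were 1055 and 857, or 55.2%. The streak list had a median of -0.58 at 16 °C against 4 °C, below matched lists. At a mean FPKM of at least 5 it was also -0.58 and lay within.

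At 24 °C against 16 °C 218 genes were higher and 95 lower. DIO2, a deiodinase that activates thyroid hormone, had FPKM 5.34 at 16 °C and 62.0 at 24 °C (3.31), and NOXO1 (2.59), RTEL1 (2.34) and ST3GAL1 (2.21) followed. HSPB9 (-3.39), JUN (-3.08), CCN2 (-3.07) and CYR61 (-2.62) were lowest. The hypoblast (0.60), streak (0.44) and ribosomal protein (0.24) lists lay above matched lists and the immediate early list (-0.48) below. Without a filter on low values the hypoblast median was 0.15 and lay within.

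**Figure D3:**
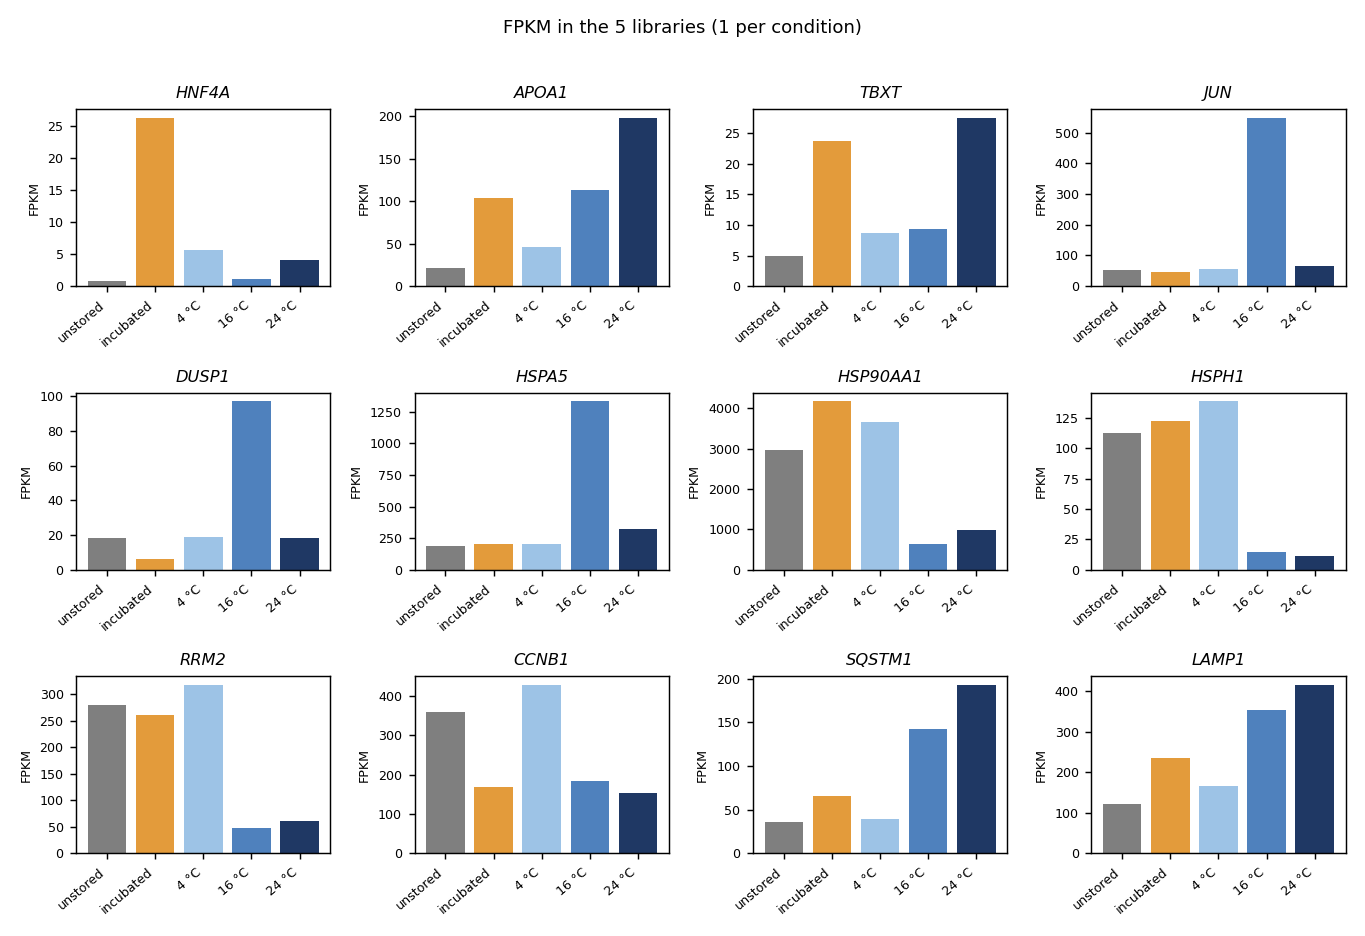
FPKM (y axis, linear from 0) of 12 genes in the 5 libraries, 1 bar per library. JUN (549), DUSP1 (97.1) and HSPA5 (1334) peak in the library stored at 16 °C, HSPH1 and RRM2 are low at 16 and 24 °C, and HNF4A is highest after incubation (26.3).

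Among 2286 genes that spanned at least 2-fold over the 3 stored libraries, 573 were ordered upward and 614 downward with temperature, 356 were highest at 16 °C and 738 were lowest there. As the libraries at 16 and 24 °C resembled each other, these counts do not separate an order with temperature from a difference between the library at 4 °C and the other stored libraries.

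The differences from unstored at 16 and 24 °C had a correlation across genes of 0.808, where unchanged libraries against the same control gave 0.5 in simulation. Genes are not independent replicates. The covariance was 0.456 against a simulated 0.037. Higher genes in common numbered 378 and lower genes 381, against 0.42 and 0.30 in the simulation and 61.4 and 55.9 for independent lists. The simulated libraries carried only the spread of the closest pair, 0.27, against 0.72 and 0.78 here. The simulated overlaps and covariance follow from that choice, and the simulated 0.5 from equal noise in all libraries. The control is 1 library and cannot be split, so part of the sharing may come from it, and how much is not known. For 4 °C the correlation was -0.086 with 16 °C and 0.026 with 24 °C. The simulated 0.5 holds for differences of equal spread and is no reference for these pairs. Their covariances were -0.0169 and 0.0056, against the simulated 0.037. Higher genes in common with 4 °C numbered 11 for 16 °C and 20 for 24 °C, against 3.5 and 4.9 for independent lists and 0.42 in the simulation, and 1 lower gene was shared with each.

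Few genes were listed at 0 in only 1 library of a pair, 8 in the incubated and 21 in the unstored library of that pair, and 11 to 22 in each library of the 3 storage comparisons with unstored. RSRP1 was listed at 0 at 24 °C with FPKM 10.8 in the unstored library. ZC3H13 was listed at 0 in the unstored library with 11.1 after incubation, and AP2B1 was listed at 0 there with 3.39 at 16 °C and 7.16 at 24 °C.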

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

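All tests weighed in this part were chosen after the result was seen, except the comparison of splits of the libraries.

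Some gene lists lay apart from matched lists in opposite directions at different storage temperatures against the unstored library. Heat shock and chaperone genes had a median log2 ratio of 0.18 at 4 °C, -0.65 at 16 °C and -0.87 at 24 °C. Histone genes had 0.24, -0.69 and -0.84, and cytosolic ribosomal protein genes had -0.0154 at 4 °C and 0.22 at 24 °C. The histone call at 4 °C was lost under 7 of 8 other settings, and those at 16 and 24 °C at a mean FPKM of at least 5 (-0.16 and -0.27). With 1 library per condition these differences were not tested. The comparisons used gene names, but most transcript accessions carried none. Among 8546 such accessions with FPKM of at least 1, 1192 differed at least 2-fold from unstored after incubation, 187 at 4 °C, 1445 at 16 °C and 1683 at 24 °C.

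The immediate early genes were higher in the library stored at 16 °C than in the others, and 15 of 24 had their highest value there, where equal libraries would give 4.8. A single factor per library moves the list and its matched lists alike. The median of 0.55 at 16 °C against 24 °C with median-ratio size factors, above a central 95% that ended at 0.20, therefore restates the observation and is no separate test of scaling. Storage at 16 °C and the handling of that library before RNA extraction cannot be told apart, because each predicts the same 15 genes and 1 library was analysed at that temperature.

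The 49 genes higher at 4 °C than in the unstored library could reflect noise, a different stage of the blastoderms or storage. Measurement noise in all of these genes would leave them within matched lists in a comparison without those libraries. Their median at 24 °C against 16 °C was 0.48 over 46 genes, above a central 95% that ended at 0.27. Of the 46, 11 were at least 2-fold higher and 1 was lower, and a median cannot tell how many of the 49 reflect noise. More advanced development or more hypoblast in the library at 4 °C predicts that the same genes are higher after incubation, and their median for incubated against 16 °C was 1.17, also above matched lists. Both comparisons use the library at 16 °C, so they are not independent of each other. Storage at 4 °C itself stays open as well, since the hypoblast median of 0.81 is what either would give and 1 library was analysed.

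The G1/S list was below matched lists at 16 and 24 °C while the G2/M list was within them. Fewer dividing cells with both lists lowered alike would leave the difference of the medians within that of matched pairs of lists, whereas a scaling factor cancels in it and was not tested. The G2/M median exceeded the G1/S median by 0.61 at 16 °C and by 0.39 at 24 °C, above a central 95% that ended at 0.29 and 0.30. The medians were thus not lowered alike in these libraries. The difference uses the same medians that prompted the question, so it is no separate test of fewer dividing cells. A candidate explanation is that cells were held in G2 or M, which could raise the G2/M transcripts. Their median was -0.33 at 24 °C, within matched lists, so this was neither shown nor excluded, as transcript levels do not count cells in a phase.

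The number of genes in which the 3 stored libraries lay apart from the other 2 by at least 1 on the log2 scale was 0, and the highest other split of the 5 libraries, 16 and 24 °C against the rest, gave 254. That number describes a structure of the libraries, 16 and 24 °C apart from the others, and is no test of storage. All 10 splits necessarily gave at least 0, so the count of splits is not informative here, and with 10 splits the share is never under 0.1.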

How the results depend on the processing

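Of 1652 list medians under the alternatives 1570 kept their call, 48 lost it and 34 gained one, and none changed sides. Most of the 1570 were lists within matched lists throughout, as 7 to 11 of 30 lists lay apart per comparison in the main setting. Only those could lose a call, so the 48 are not a share of 1652. The 2 scaling settings could change few calls, because a factor per library moves a list and its matched lists alike. Of 225 counts 131 stayed within 1.5 times their value and 94 moved. Of 2287 values of genes that the rule took or the text names 2010 moved by less than the standard deviation of the closest pair of libraries, 0.27, and 277 moved by more. The 296 values without a filter, 248 at a mean FPKM of at least 5 and 265 among genes of 1 matched accession could not move. Those settings choose genes and leave a gene's own ratio unaltered. No gene at least 2-fold different changed direction. A pseudocount cannot turn a ratio, and scaling factors far below 2-fold cannot reverse a 2-fold difference. Only the highest row per gene could have done so. The highest row per gene moved no count. Leaving out the filter could not move one, because a difference of 1 on the log2(FPKM + 1) scale needs FPKM of at least 1 in 1 library. The 23 counts without a filter are therefore among the 131 by construction. Depth is not known from FPKM, so its effect was not measured. No paired analysis was possible because each condition had 1 library. Where a value changed, the cause was not tested, except that fewer or more genes or accessions enter by construction. Lists with fewer than 3 members left at a mean FPKM of at least 5 gave no value there.

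Numbers of genes higher and lower are given in this order. With a pseudocount of 0.1 they were 1096 and 362 for incubated against unstored, 174 and 59 for 4 °C, 476 and 247 for 24 against 16 °C, and the higher genes were 952 for 16 °C and 874 for 16 against 4 °C. All 3 stored libraries shared 47 and 3 against unstored, 63 and 199 against incubated, and 1 higher gene against both, and 1 gene separated the stored libraries from the other 2. With a pseudocount of 5 they were 160 and 68 for incubated against unstored, 6 and 0 for 4 °C, 160 and 312 for 16 °C, 260 and 338 for 24 °C, 227 and 490 for 24 against 4 °C, 173 and 491 for 16 against 4 °C and 46 and 25 for 24 against 16 °C. The stored libraries then shared 2 higher genes against unstored and 3 and 20 against incubated, and 540 of 1000 genes with a range of at least 2-fold were ordered with temperature.

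At a mean FPKM of at least 5 the higher genes were 337 for incubated against unstored, 27 for 4 °C with 1 lower, 358 for 16 °C, 464 for 24 °C, 426 for 24 against 4 °C, 332 for 16 against 4 °C and 138 for 24 against 16 °C with 56 lower. The stored libraries shared 42 lower genes against incubated, and 790 genes were ordered. Median-ratio size factors gave 31 and 13 for 4 °C and 1 lower gene shared against unstored. Rescaling to 1000000 gave 77 and 31 for 4 °C, 388 and 168 for 24 against 16 °C, and higher genes of 992 for 16 °C, 1295 for 24 °C, 1280 for 24 against 4 °C and 1055 for 16 against 4 °C, with 17 and 1 shared against unstored and 35 and 174 against incubated. Among genes of 1 matched accession 4 were lower at 4 °C.

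Over all transcript accessions, chosen after seeing the data, the numbers were 1537 and 703 for incubated against unstored, 172 and 111 for 4 °C, 1546 and 1373 for 16 °C, 1962 and 1377 for 24 °C, 1824 and 1902 for 24 against 4 °C, 1623 and 2045 for 16 against 4 °C and 572 and 408 for 24 against 16 °C. The stored libraries shared 31 and 1 against unstored, 134 and 255 against incubated and 2 higher against both, 2 separated them from the other 2 libraries, and 2583 of 5358 with the range were ordered. Leaving out 4 °C gave 378 and 381 against unstored, 211 and 592 against incubated and 91 and 181 against both. Leaving out 16 °C gave 20 and 1 against unstored and 1 higher against both, and leaving out 24 °C gave 1 lower against unstored and 41 and 176 against incubated.

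With a pseudocount of 0.1, lists that no longer lay apart were for 4 °C against unstored histone 0.28, and for 16 against 4 °C pluripotency -0.52, antioxidant -0.50, and for 24 against 16 °C autophagy and lysosome 0.24. With a pseudocount of 5, lists that no longer lay apart were for 4 °C against unstored histone 0.12, and for 16 against 4 °C pluripotency -0.36, and for 24 against 16 °C oocyte -0.10, autophagy and lysosome 0.14, histone -0.056. Without a filter, lists that no longer lay apart were for 4 °C against unstored histone 0.22, and for 16 °C against unstored autophagy and lysosome 0.16, and for 24 °C against unstored unfolded protein response 0.21, hypoblast 0.25, and for 24 against 4 °C unfolded protein response 0.11, proteasome 0.0083, and for 16 against 4 °C pluripotency -0.45, antioxidant -0.36, and for 24 against 16 °C hypoblast 0.15, oocyte -0.12, egg white 0.15. At a mean FPKM of at least 5, lists that no longer lay apart were for incubated against unstored histone -0.25, and for 4 °C against unstored histone 0.0769, and for 16 °C against unstored histone -0.16, and for 24 °C against unstored histone -0.27, and for 24 against 4 °C histone -0.74, and for 16 against 4 °C streak -0.58, histone -0.25, and for 24 against 16 °C apoptosis initiation 0.27, autophagy and lysosome 0.19, histone -0.0035. With median-ratio size factors, lists that no longer lay apart were for 4 °C against unstored histone 0.13, and for 16 against 4 °C pluripotency -0.38, antioxidant -0.36. After rescaling to 1000000, lists that no longer lay apart were for 4 °C against unstored histone 0.18, and for 16 against 4 °C pluripotency -0.30, antioxidant -0.28. With the highest row per gene, lists that no longer lay apart were for 16 against 4 °C pluripotency -0.51, antioxidant -0.49. Among genes of 1 matched accession, lists that no longer lay apart were for incubated against unstored G2/M -0.25, hypoblast 0.58, and for 4 °C against unstored G2/M 0.14, epithelial 0.21, histone 0.24, and for 24 against 4 °C apoptosis initiation 0.27, and for 16 against 4 °C pluripotency -0.51, antioxidant -0.43, and for 24 against 16 °C oxidative phosphorylation 0.12, autophagy and lysosome 0.14.

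With a pseudocount of 0.1, lists that newly lay apart were for 4 °C against unstored glycolysis and hypoxia 0.17, and for 24 °C against unstored p53 targets 0.46, white blood cell 1.38. With a pseudocount of 5, lists that newly lay apart were for 4 °C against unstored glycolysis and hypoxia 0.13, and for 16 °C against unstored erythroid -0.36, and for 24 °C against unstored p53 targets 0.24, and for 24 against 4 °C antioxidant -0.39. Without a filter, lists that newly lay apart were for 4 °C against unstored egg white -0.0711, and for 24 °C against unstored oocyte -0.19, and for 24 against 4 °C oocyte -0.46, muscle and neural -0.29, and for 16 against 4 °C oocyte -0.26, erythroid -0.47, muscle and neural -0.25, and for 24 against 16 °C muscle and neural -0.0924. At a mean FPKM of at least 5, lists that newly lay apart were for incubated against unstored immediate early -0.28, and for 4 °C against unstored glycolysis and hypoxia 0.16, and for 16 °C against unstored unfolded protein response 0.25, and for 24 against 4 °C pluripotency -0.65, and for 16 against 4 °C unfolded protein response 0.15, hypoblast -0.77, erythroid -1.04. With median-ratio size factors, lists that newly lay apart were for 16 against 4 °C germ cell -0.55. After rescaling to 1000000, lists that newly lay apart were for 4 °C against unstored glycolysis and hypoxia 0.0715, and for 24 °C against unstored p53 targets 0.53. With the highest row per gene, lists that newly lay apart were for 16 °C against unstored erythroid -0.60, and for 16 against 4 °C epithelial -0.57, and for 24 against 16 °C G1/S -0.16, p53 targets 0.29. Among genes of 1 matched accession, lists that newly lay apart were for 16 °C against unstored germ cell -0.48, and for 24 °C against unstored p53 targets 0.43, and for 16 against 4 °C germ cell -0.66, hypoblast -0.72, and for 24 against 16 °C G1/S -0.16.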

Other observations

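Gene groups were also compared between storage temperatures. For 24 °C against 4 °C, the medians of apoptosis initiation (0.33), the unfolded protein response (0.16), ribosomal proteins (0.25), autophagy and lysosome (0.28) and the egg white list (1.93) lay above matched lists, and those of G1/S (-0.85), chaperones (-0.98) and histones (-1.10) below. These lists also lay apart for 24 °C against unstored, a comparison that shares the library at 24 °C and is therefore not independent. The hypoblast list (-0.17) and the muscle and neural list (-0.34), apart at 24 °C against unstored, lay within matched lists against 4 °C. The calls of histones at a mean FPKM of at least 5 (-0.74), of apoptosis initiation among genes of 1 matched accession (0.27) and of the unfolded protein response without a filter (0.11) were lost. The proteasome list also lay above, at a median of 0.0083 and a mean of -0.0883, a call lost without a filter. For 16 °C against 4 °C the pluripotency (-0.51) and antioxidant (-0.49) lists lay below, calls that most other settings did not keep. For 24 °C against 16 °C the egg white list lay above and the histone list below. The first call was lost without a filter (0.15), the second with a pseudocount of 5 (-0.056) and at a mean FPKM of at least 5 (-0.0035). In the same comparison apoptosis initiation (0.29), oxidative phosphorylation (0.13) and autophagy and lysosome (0.24) also lay above, and the oocyte list of 5 genes (-0.39) below. Of 8 other settings, 4 ended the autophagy and lysosome call, 2 the oocyte call, and 1 each the calls of apoptosis initiation and oxidative phosphorylation.

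The list of cold-inducible RNA-binding proteins lay within matched lists in all comparisons. Against the library incubated at 37 °C its median was 0.35 at 4 °C, with 4 of 18 genes at least 2-fold higher and none lower. At 16 °C its median was 0.22, with 3 higher and 4 lower, while its mean was -0.10. Both medians lay near the upper end of matched lists (0.37 and 0.24). RBM3 had FPKM 299 in the unstored library, 206 at 4 °C, 246 at 16 °C and 176 at 24 °C, and 101 after incubation. None of the 18 genes of that list was at least 2-fold higher than unstored at any storage temperature, and 5 were lower at 16 °C and 5 at 24 °C. The death receptor gene FAS was 1.81 higher on the log2 scale at 24 °C than in the unstored library, and the adaptor TRADD 1.01 higher at 16 °C.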
